A study of Mus musculus with 8 samples.

How the data were processed

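RNA was measured in 8 preparations of mouse mammary epithelial cells, 4 from control mice and 4 from mice that express miR-150 constitutively, each from a separate mouse per the sample titles. Per the labels' protocols, glands were harvested on lactation day 2, epithelial cells depleted of fat were prepared from upper inguinal glands, total RNA was extracted with Trizol, and the RNA was labelled with a FlashTag biotin kit before hybridisation to the Affymetrix Mouse Transcriptome Array 1.0, a 1-colour array. FlashTag kits are usual for small RNA arrays. The labels were the only source for the kit, so its use here could not be checked. The kit bears on what the Mir150 cluster and the other intensities measure. The deposited values are linear intensities, 1 per transcript cluster and array, for 65770 clusters. How the authors corrected background, normalized and summarised these intensities is not given in the sources used here. The 8 columns have nearly equal quantiles, with array medians of 34.8 to 36.0 and values from 19.6 to 19868. Scanner files and detection calls were not used here, so no level is given as a bound against background. The median cluster lies near the lowest value, and folds of dim genes can be understated, which was not measured. Folds of the most abundant milk protein genes, which lie near the upper end of the scale, can be understated as well. For arrays, their number limits the precision.

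Genes were named through the platform annotation. It lists 32585 of the clusters, 30439 with exactly 1 gene symbol and 2146 with several, and 33185 clusters are unnamed here. Symbols were brought up to date with a RefSeq gene table of assembly GRCm38.p6, through the Entrez identifier for 22653 clusters, a current symbol for 7476 and a synonym for 308; 2 kept the platform's name, and 1135 names changed. The array's genome build is not given in the sources used here, so that table served only for names and for the order of neighbouring genes, and no coordinates are printed. Genes read only by clusters with several symbols, among them Srebf1, Scd2 and Prlr, have no named value.

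Intensities were converted to log2, with no pseudocount. Tested were clusters with exactly 1 symbol and a mean log2 over the 8 arrays above the median of all clusters, 5.16, which is an intensity of 35.7; 19266 clusters of 19085 genes passed. Genotypes were compared with limma (lmFit and eBayes, two-sided, no covariate) and Benjamini-Hochberg adjustment over all clusters tested, with a threshold of 0.05. Where a gene had several clusters, the brightest stands for it. Adjusted p-values of genes are from limma; SE is limma's moderated standard error; intervals are 95% intervals. The Mir150 cluster was also compared with an exact permutation test over the 70 assignments of arrays to genotypes, whose smallest two-sided p is 0.029. The replicate numbers follow the order of deposition and pair nothing.

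In all, 31 gene lists with 655 entries were written before the data were examined, as were the sample groups, the tests, the alternatives and the rule for naming genes; 563 entries are on the array. The 29 lists with at least 5 tested members were compared with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Camera asks whether a list's members shifted up or down against other genes, and fry whether they moved on balance in a single direction. A list's shift is the mean log2 difference of its tested members, with an interval over arrays. An exact permutation test of each list's mean per array was added after the data were seen. The rule for naming genes took the 12 largest rises and 12 largest falls among genes past the threshold, leaving out predicted and small RNA models, then Mir150, the genes the study is known for, and up to 4 members per list with the smallest p. Further members are named where a list is described, chosen after their values were seen.

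The gene test was tested on simulated data with the control means and residual spreads of the same 19266 clusters, of which 200 were changed. It recovered 100% of falls of 2 on the log2 scale, 90% of falls and 97.5% of rises of 1, and 67.5% of falls and 77.5% of rises of 0.5; 7 of 180 calls, 3.9%, were false. Of 29 unchanged lists, 1 was called at the preset correlation. Genes were simulated independently, so this count does not show how often unchanged lists of correlated genes are called. Alternatives were quantile normalization, median centring, mouse age or the number in the description field as a covariate, array weights, leaving out each array, other filters, other thresholds, other choices of cluster, a variance trend with robust estimation, and the other list tests. A planned test of genes with a miR-150 seed site in the 3′ untranslated region was not run, since no such sequences were used here. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.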

Results

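Gene expression was profiled on arrays in mammary epithelial cells of mice on lactation day 2. The question, as the series states its design, was how cells that express miR-150 constitutively differ from controls. The miR-150 mice carried a conditional miR-150 transgene on both alleles together with WAP-Cre, a Cre recombinase driven by the whey acidic protein promoter, which is active in the milk-producing epithelium of late pregnancy and lactation. Control mice carried WAP-Cre without the transgene. Each genotype had 4 arrays, 1 per mouse, on a mixed C57BL6 and FVB background. Control mice were 77 to 86 days old and miR-150 mice 65 to 80, and 3 of the 4 miR-150 mice were younger than every control. Array medians were 34.8 to 36.0 in intensity units, in deposited values whose normalization is not known, and the maximum was 15508 on miR-150 replicate 4 against 18681 to 19868 on the other arrays.

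The cluster named for Mir150, the miRNA the mice were made to express, was higher in every miR-150 mouse than in any control. Its geometric mean intensity was 63.2 in controls and 151.5 in miR-150 mice, with log2 values of 5.98 ± 0.22 and 7.24 ± 0.21 (SD, n = 4 each). The difference was 2.4-fold (95% interval 1.96 to 2.93, limma adjusted p = 0.000494, exact permutation p = 0.029, the smallest this design can give). Whether the cluster reads the precursor or the mature miRNA is not given in the sources used here.

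Expression differed widely between the genotypes. Of 19266 clusters tested, 4244 (22%) passed the threshold, 2441 higher and 1803 lower in miR-150 mice, and 379 of them differed at least 2-fold, 173 higher and 206 lower. The median absolute log2 difference among clusters that passed was 0.40. In miR-150 mice 20 of 22 fatty acid synthesis genes, 17 of 19 cholesterol synthesis genes and 26 of 26 cell cycle genes fell, while 20 of 26 genes known from mammary involution and the acute phase rose. As lists these 4 passed camera at the preset correlation and not at an estimated one (adjusted p = 0.185 to 0.218). The first principal component held 64.8% of the variance and separated the genotypes; correlations between arrays were 0.986 to 0.994 within and 0.956 to 0.980 between genotypes. With the number in the description field as a covariate, whose meaning is not stated, 2070 clusters passed, 1056 higher and 1014 lower. Like age, that number largely went with genotype.

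**Figure D1:**
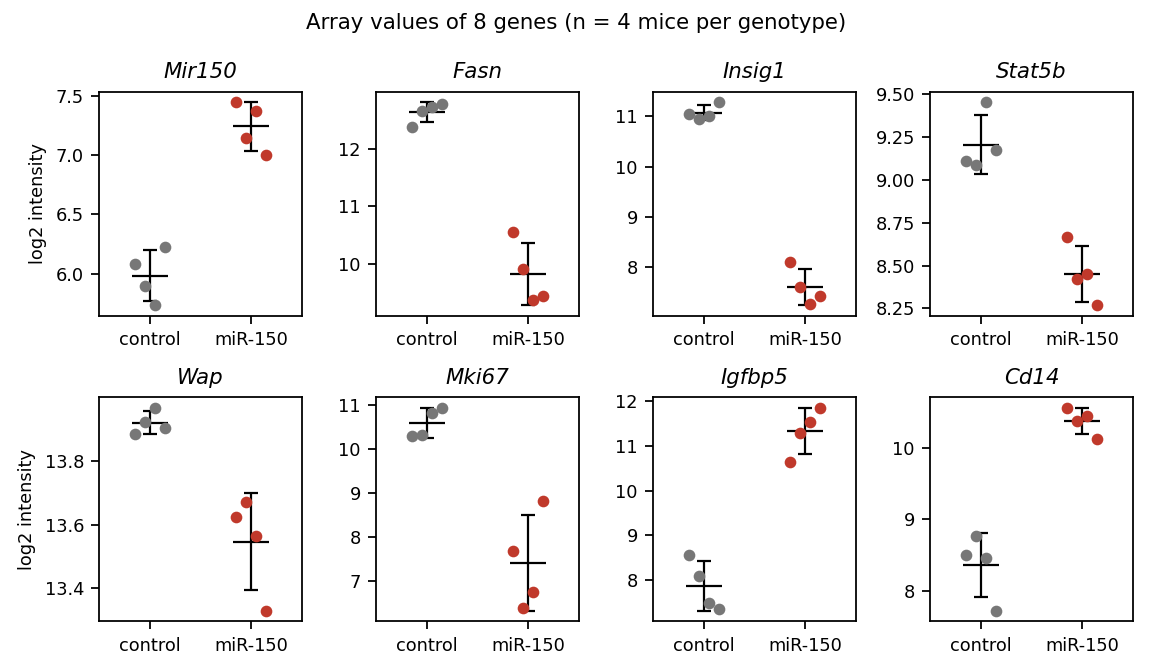
Log2 intensity of 8 genes on each array, with 1 point per mouse, for control and miR-150 mice; the horizontal bar is the mean and the whisker the SD (n = 4), and each panel has its own log2 axis. Mir150, Igfbp5 and Cd14 were higher and Fasn, Insig1, Stat5b, Wap and Mki67 lower on all 4 miR-150 arrays than on any control array.

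Genes of de novo fatty acid synthesis fell together in miR-150 mice. Fatty acid synthase, Fasn, fell 7.08-fold (log2 difference -2.82 ± 0.24 SE, adjusted p = 0.000304), from an intensity of 6389 to 903. The mitochondrial citrate carrier Slc25a1, which exports the carbon for lipid synthesis, fell 6.07-fold (95% interval 4.89 to 7.53), ATP citrate lyase Acly 3.96-fold (2.67 to 5.88), the elongase Elovl6 3.78-fold (2.86 to 4.99), the desaturase Fads1 2.73-fold (2.34 to 3.18) and acetyl-CoA carboxylase Acaca 2.66-fold (2.14 to 3.29). Of the 22 members tested, 20 fell, Idh1 rose (0.46 ± 0.10) and 1 did not pass; adjusted over the list alone the counts were 20 and 1. The mean shift was -1.10 (-1.38 to -0.81), with a camera adjusted p of 8.19e-13 and adjusted p = 0.218 with an estimated correlation. Not all members moved alike: the stearoyl-CoA desaturase Scd1 fell by 0.27 ± 0.08 and the carbohydrate-responsive transcription factor Mlxipl by 0.17 ± 0.04 on the log2 scale.

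Cholesterol synthesis genes showed a fall of similar size. Insig1, a sterol-regulated protein that holds the SREBP transcription factors in the endoplasmic reticulum, fell 11.1-fold (8.51 to 14.4, adjusted p = 6.37e-05). The enzymes Idi1, Cyp51 and Fdps fell by 2.07 ± 0.13, 1.79 ± 0.07 and 1.79 ± 0.12, and the transcription factor Srebf2 by 0.48 ± 0.09 on the log2 scale. Of 19 members, 17 fell, 0 rose and 2 did not pass, Sc5d (-0.26 ± 0.08) and Ggps1 (0.03 ± 0.06); adjusted over the list alone 18 fell. Their mean shift was -1.16 (-1.34 to -0.99, camera adjusted p = 1.07e-14, adjusted p = 0.185 with an estimated correlation). On the same arrays the luminal epithelium markers shifted by 0.57 (0.34 to 0.80), the macrophage and dendritic cell markers by 0.35 (0.08 to 0.63) and the adipocyte markers by -0.14 (-0.31 to 0.04), or -0.069 without control replicate 3.

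The steps that take up fatty acids and store or secrete lipid were mixed. Lipoprotein lipase Lpl fell 2.76-fold, the phosphatidate phosphatase Lpin1 by 2.15 ± 0.27 on the log2 scale and the fatty acid binding protein Fabp3 1.94-fold (1.64 to 2.30), whereas the acyltransferase Agpat3 rose 1.85-fold (1.61 to 2.12) and Plin2, a coat protein of lipid droplets, rose 1.69-fold (1.5 to 1.9). Of 22 members 9 fell, 2 rose and 11 did not pass, and adjusted over the list alone 11 fell and 3 rose. The mean shift was -0.34 (-0.48 to -0.19, camera adjusted p = 0.0292, adjusted p = 0.398 with an estimated correlation). The camera call was lost with age as a covariate (-0.45), without the filter and without miR-150 replicate 2 (-0.33).

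**Figure D2:**
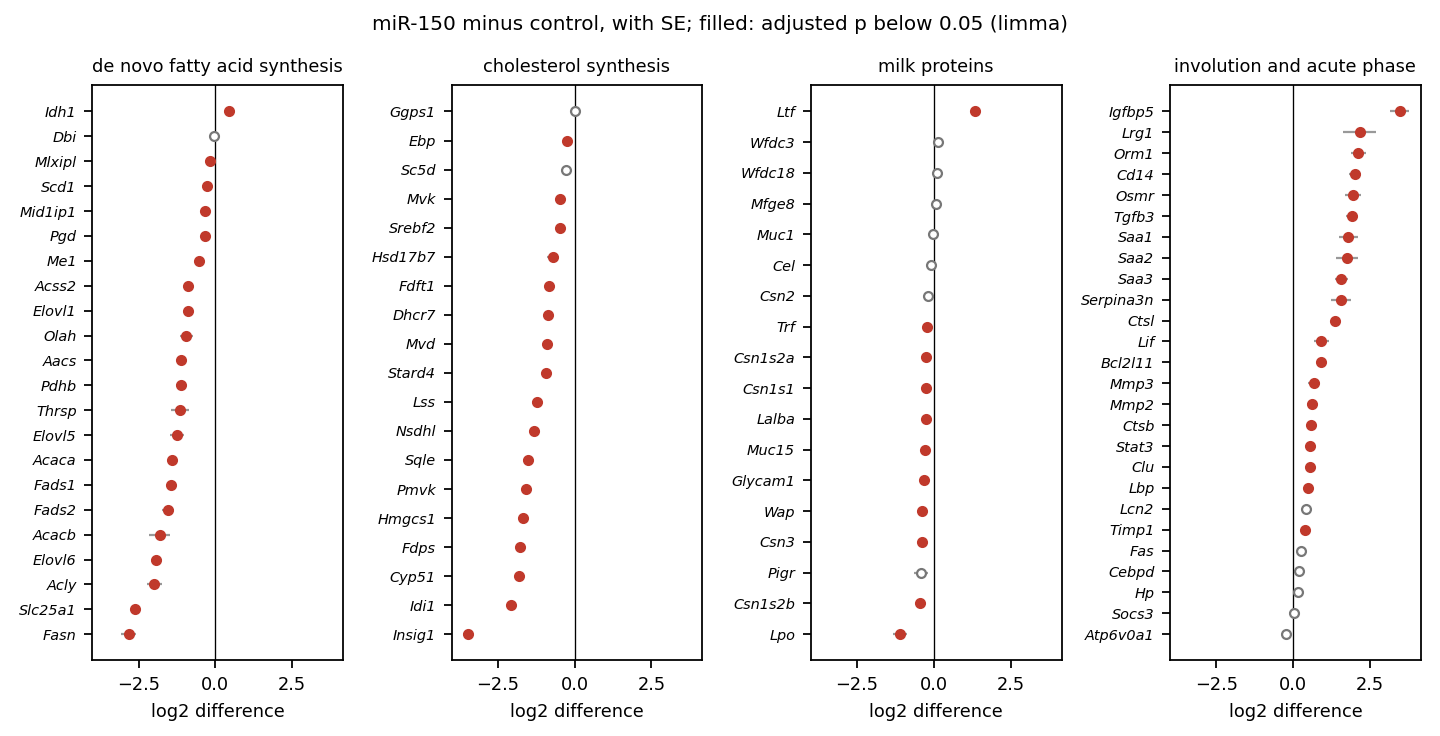
Log2 difference, miR-150 minus control, of each tested member of 4 gene lists, with limma's SE (n = 4 arrays per genotype). Filled points passed an adjusted p of 0.05 and open points did not; 20 of 22 fatty acid synthesis genes and 17 of 19 cholesterol synthesis genes fell, while 20 of 26 involution and acute phase genes rose.

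Among the genes this study is known for, which partly overlap those above, 9 of 14 fell, 1 rose and 4 did not pass; adjusted over the list alone 12 fell and 1 rose. This list was drawn from the study itself and is not independent evidence of its direction (mean shift -0.77, -1.10 to -0.45, camera adjusted p = 1.48e-05, adjusted p = 0.368 with an estimated correlation). The lipogenic protein gene Thrsp fell 2.24-fold (1.41 to 3.56, adjusted p = 0.0225) and Olah, the thioesterase that releases medium-chain fatty acids, 1.92-fold (1.37 to 2.68, adjusted p = 0.0136). Values of Xdh (-0.41 ± 0.15, adjusted p = 0.0826), Btn1a1 (-0.24 ± 0.16), Csn2 (-0.20 ± 0.07) and Elf5 (-0.20 ± 0.07, adjusted p = 0.0622) did not pass. Btn1a1 read 11.235 log2 on miR-150 replicate 4, against 11.80 to 12.07 on the other miR-150 arrays and 11.93 to 12.05 in controls. With age as a covariate Csn2 (-0.31), Elf5 (-0.34) and Btn1a1 (-0.62) passed. The age slope behind these calls leans most on miR-150 replicate 4, aged 80 days against 65 to 67 for the other miR-150 mice. Thrsp did not pass without control replicate 2 (-1.11) or 3 (-1.05). Thrsp (-1.23), Olah (-1.02), Wap (-0.38) and Lalba (-0.34) did not pass with the description number as a covariate.

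Milk protein genes fell by small amounts from very high levels, beside a luminal epithelium marker shift of 0.57 (0.34 to 0.80) on the same arrays. Wap, the whey acidic protein, fell 1.30-fold (1.15 to 1.45, adjusted p = 0.00764), Glycam1 1.24-fold (1.13 to 1.35, adjusted p = 0.00526) and Lalba, the alpha-lactalbumin that lactose synthase needs, 1.20-fold (1.08 to 1.33, adjusted p = 0.0222). Lactoperoxidase, Lpo, fell 2.14-fold (1.52 to 3.01; -0.96 with age as a covariate, which did not pass), while lactotransferrin, Ltf, rose 2.54-fold (2.10 to 3.06). Of 18 members 10 fell, 1 rose and 7 did not pass, and adjusted over the list alone 11 fell; the mean shift was -0.16 (-0.24 to -0.09, camera adjusted p = 0.00526, adjusted p = 0.368 with an estimated correlation). The call for Lalba was also lost without control replicate 2 (-0.26) or 3 (-0.24), without miR-150 replicate 3 (-0.24), after quantile normalization (-0.17) and with a variance trend and robust estimation (-0.26).

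For lactose synthesis and glucose uptake, 5 of 12 members fell and 7 did not pass, with 5 adjusted over the list alone, and the list did not pass camera (mean shift -0.17, -0.28 to -0.06, adjusted p = 0.0804). It passed after quantile normalization (-0.21), with the 75th percentile filter (-0.17), and without miR-150 replicate 1 (-0.20) or 3 (-0.19). Slc35a2, the Golgi transporter of UDP-galactose, fell 1.43-fold (1.32 to 1.54); B4galt1 (-0.52 ± 0.11) and hexokinase 2, Hk2 (-0.68 ± 0.11), fell too but did not pass with the description number as a covariate (-0.37 and -0.53). Among transporters of calcium, zinc, phosphate and amino acids, the phosphate cotransporter Slc34a2 fell 5.17-fold (2.99 to 8.92), the plasma membrane calcium pump Atp2b2 4.56-fold (3.12 to 6.66), the amino acid transporter Slc7a8 2.88-fold (2.30 to 3.61) and the zinc transporter Slc30a2 2.13-fold (1.67 to 2.72). In that list 7 of 19 fell, 1 rose and 11 did not pass; adjusted over the list alone 8 fell and 3 rose (mean shift -0.44, -0.60 to -0.29, camera adjusted p = 0.0364, adjusted p = 0.368 with an estimated correlation). Its camera call was lost with age as a covariate (-0.55), without the filter, and without control replicate 1 (-0.45) or miR-150 replicate 2 (-0.43). Luminal epithelium markers shifted by 0.57 (0.34 to 0.80) and macrophage and dendritic cell markers by 0.35 (0.08 to 0.63) on the same arrays.

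Both STAT5 genes, which carry the prolactin signal, fell: Stat5a 1.74-fold (1.41 to 2.14, adjusted p = 0.0036) and Stat5b 1.69-fold (1.43 to 1.99, adjusted p = 0.00164). The kinase Akt1 fell 1.5-fold (1.38 to 1.63) and the glucocorticoid receptor Nr3c1 1.27-fold (1.18 to 1.37), whereas the receptor Igf1r rose 1.29-fold (1.19 to 1.41) and Jak2 by 0.43 ± 0.12 on the log2 scale. The prolactin and STAT5 list as a whole did not pass camera (4 of 21 rose, 4 fell and 13 did not pass; 4 and 5 adjusted over the list alone; mean shift -0.10, camera adjusted p = 0.291). The STAT5-induced genes Cish (-0.22 ± 0.17) and Socs2 (-0.13 ± 0.06) did not pass.

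All 26 cell cycle genes tested fell, also adjusted over the list alone. The proliferation marker Mki67 fell 9.07-fold (4.30 to 19.1, adjusted p = 0.00229), the ribonucleotide reductase subunit Rrm2 3.23-fold (2.48 to 4.21) and the replication helicase genes Mcm6, Mcm2 and Mcm4 1.80-, 1.78- and 1.70-fold. The mean shift was -1.04 (-1.40 to -0.67, camera adjusted p = 9.02e-18, adjusted p = 0.218 with an estimated correlation). With age as a covariate it was -0.79, and camera at the preset correlation still called the list. The list read -0.670 on miR-150 replicate 4, whose age lay among the controls', and -0.985 to -1.251 on the other miR-150 arrays. A part played by age cannot be told apart. The cell cycle fall and those of the next 2 lists stood beside shifts of 0.57 (0.34 to 0.80) in luminal epithelium and 0.35 (0.08 to 0.63) in macrophage and dendritic cell markers on the same arrays. Genes of oxidative phosphorylation fell less: 17 of 24 fell, 0 rose and 7 did not pass (19 adjusted over the list alone), among them Sdhb 1.47-fold (1.36 to 1.59), Cyc1 1.46-fold (1.37 to 1.56) and Atp5a1 1.32-fold (1.23 to 1.43). Their mean shift was -0.32 (-0.41 to -0.22, camera adjusted p = 5.25e-09, adjusted p = 0.218 with an estimated correlation). Of 18 amino acid response genes, targets of the transcription factor ATF4, 7 fell and 11 did not pass, with 8 adjusted over the list alone; Aldh18a1 fell 2.56-fold (2.06 to 3.17), Phgdh, which opens serine synthesis, 1.90-fold (1.56 to 2.31) and the asparagine synthetase Asns 1.62-fold (1.37 to 1.90). That list shifted by -0.29 (-0.44 to -0.14, camera adjusted p = 0.0317, adjusted p = 0.398 with an estimated correlation), and the call was lost with age as a covariate (-0.26), without the filter and without miR-150 replicate 2 (-0.27).

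Genes of involution and the acute phase rose in miR-150 mice. Igfbp5, an insulin-like growth factor binding protein that rises when milk removal stops, rose 11.1-fold (6.73 to 18.3, adjusted p = 0.000371), from an intensity of 233 to 2586. The lipopolysaccharide co-receptor Cd14 rose 4.04-fold (2.92 to 5.57), Tgfb3 3.75-fold (2.87 to 4.90) and the lysosomal protease Ctsl 2.58-fold (2.21 to 3.01); Stat3, which drives involution, rose by 0.56 ± 0.11 on the log2 scale, while its target Socs3 read 0.04 ± 0.15. Of 26 members 20 rose, 0 fell and 6 did not pass, and 23 rose adjusted over the list alone. Together they shifted by 1.09 (0.74 to 1.43, camera adjusted p = 1.45e-12, adjusted p = 0.218 with an estimated correlation). On the same arrays the macrophage and dendritic cell markers shifted by 0.35 (0.08 to 0.63), and S100a8, a neutrophil gene, rose 2.95-fold (2.08 to 4.17).

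Of 23 interferon response genes tested, 10 rose, Bst2 fell (-0.42 ± 0.11) and 12 did not pass, with 11 and 1 adjusted over the list alone. The guanylate-binding protein gene Gbp2 rose 2.04-fold (1.61 to 2.59) and Xaf1 by 0.52 ± 0.09 on the log2 scale, and Ifit3 read 0.00 ± 0.12. The mean shift was 0.33 (0.05 to 0.61, camera adjusted p = 0.000244, adjusted p = 0.477 with an estimated correlation, fry adjusted p = 0.0612), beside the macrophage shift given above. Of 14 tight junction genes 8 rose, Cldn8 fell (-0.43 ± 0.13) and 5 did not pass, with 9 and 1 adjusted over the list alone (mean shift 0.42, 0.21 to 0.63, camera adjusted p = 0.000963, adjusted p = 0.368 with an estimated correlation). Cldn4 rose 2.47-fold (2.00 to 3.05) and Marveld2, tricellulin, 1.48-fold (1.33 to 1.64); Cldn3 rose 2.05-fold (1.43 to 2.94) but did not pass with the description number as a covariate (0.70). Cldn3 and Cldn4 are also in the luminal epithelium list, which shifted by 0.57 (0.34 to 0.80) on the same arrays.

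Luminal epithelium markers rose: 10 of 19 rose, 0 fell and 9 did not pass, with 11 higher and 3 lower adjusted over the list alone (mean shift 0.57, 0.34 to 0.80, camera adjusted p = 0.000963, adjusted p = 0.361 with an estimated correlation). The receptor tyrosine kinase gene Kit, a marker of luminal progenitors, rose 6.05-fold (3.47 to 10.6) and the keratin gene Krt18 2.36-fold (1.95 to 2.85); Krt8 rose 1.95-fold (1.54 to 2.48) but did not pass with the description number as a covariate (0.74). Macrophage and dendritic cell markers also rose, 6 of 18 with 0 falling and 12 not passing, and 9 adjusted over the list alone (camera adjusted p = 3.04e-05, adjusted p = 0.398 with an estimated correlation). Cd68, a lysosomal protein of macrophages, rose 1.91-fold (1.53 to 2.39), Fcer1g 1.38-fold (1.22 to 1.57) and Adgre1, which encodes F4/80, by 0.23 ± 0.06 on the log2 scale. With the description number as a covariate Fcer1g (0.43) did not pass.

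The remaining cell type lists did not pass camera with all arrays and no covariate. With the description number as a covariate myoepithelium (-0.42), adipocytes (-0.28) and endothelium (-0.24) passed, as did endothelium without control replicate 2 (-0.16) and fibroblasts with age as a covariate (0.28) or without control replicate 1 (0.23). Myoepithelium also passed without miR-150 replicate 4 (-0.26). No member of the myoepithelium (16 tested, mean shift -0.16, -0.62 to 0.31), T and NK cell (16, -0.02) or B and plasma cell (12, -0.09) lists passed, also adjusted over the list alone. The control median intensity was 46.4 for T and NK cell and 51.1 for B and plasma cell markers, near the dim end of the scale. A change in these cells could therefore be missed. The B and plasma cell shift was -0.045 without miR-150 replicate 4 and -0.184 with age as a covariate. Of 15 adipocyte markers Lpl and Pparg fell and Lipe rose, with the same counts of 2 and 1 adjusted over the list alone, and Pparg (-0.48 ± 0.14) lost its call without the filter, with the description number as a covariate and in 5 of the fits that left out an array. Of 17 fibroblast markers 2 rose (1 adjusted over the list alone), of 17 endothelial markers 1 rose and 3 fell (1 and 3), of 13 skeletal muscle genes 1 rose (1) and of 10 neutrophil genes S100a8 and Ltf rose (2), the latter also a milk protein of the epithelium. The neutrophil median was -0.03 and the mean 0.28, and the other 8 members did not pass. Among the endothelial and muscle calls, Cldn5 (0.50), Ptprb (-0.22), Gpihbp1 (-0.26) and Mb (0.18) did not pass with age as a covariate. The fibroblast gene Mfap5 (0.325) did not pass with the description number as a covariate. Camera adjusted p-values were 0.192 for myoepithelium, fibroblasts and endothelium, 0.307 for adipocytes, 0.463 for T and NK cells, 0.398 for B and plasma cells, 0.444 for skeletal muscle and 0.511 for neutrophils. Red blood cell and mitochondrially encoded genes, with 3 and 2 members tested, were not tested as lists, and 0 of them passed.

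Genes reported as miR-150 targets moved both ways. Of 17 tested, 5 rose, 4 fell and 8 did not pass (6 and 4 adjusted over the list alone); the median was 0.09 and the mean -0.14 (-0.23 to -0.05), of opposite sign. The list did not pass camera (adjusted p = 0.444) and passed the exact permutation test of its mean (adjusted p = 0.044). The 4 that fell, Fasn, Acaca, Olah and Stat5b, are targets this study is known for and are not independent evidence. The mean in the exact test includes them, and no other member fell past the threshold. The transcription factor Foxp1, a target known from lymphocytes, rose 1.28-fold (1.19 to 1.38), and Gab1, Cxcr4, Prkca and Sp1 rose as well.

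Further lists did not pass camera with all arrays and no covariate either. For the unfolded protein response, 2 of 23 members rose, 1 fell and 20 did not pass, and 0 passed adjusted over the list alone (mean shift 0.07, -0.35 to 0.50, camera adjusted p = 0.628). That list passed with the description number as a covariate (0.31) and without miR-150 replicate 4 (0.23). For immediate early and dissociation stress genes, 3 of 21 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.628); Zfp36 fell 1.75-fold (1.42 to 2.15) and Ccn1 rose 2.24-fold (1.78 to 2.82). Glycolysis and hypoxia genes had 3 rises and 7 falls in 20, also adjusted over the list alone (mean shift -0.13, -0.22 to -0.04, camera adjusted p = 0.166), with Aldoc 2.48-fold lower (1.92 to 3.20) and Aldoa 1.32-fold higher (1.19 to 1.46). They passed without miR-150 replicate 4 (-0.14). Of 15 ribosomal protein genes, 1 rose and 0 passed adjusted over the list alone (camera adjusted p = 0.181); the list passed without miR-150 replicate 4 (0.12).

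**Figure D3:**
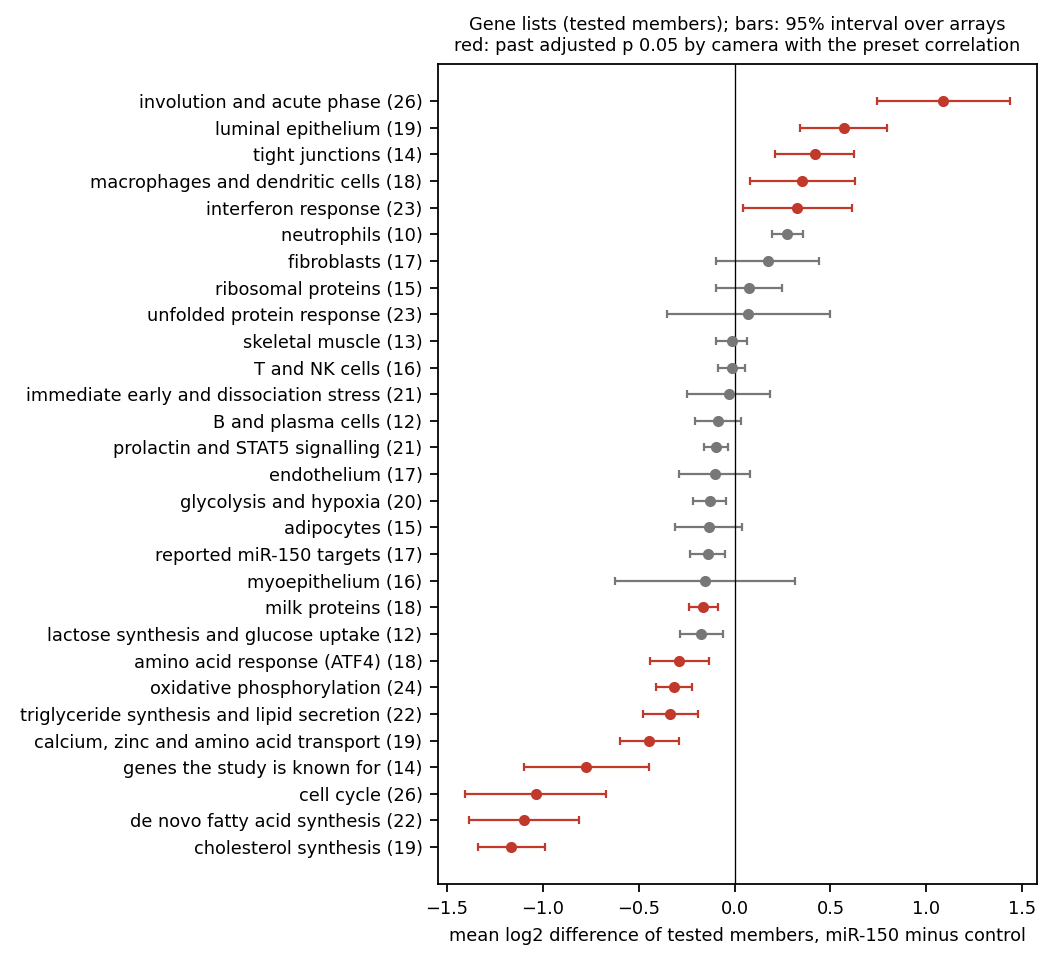
Mean log2 difference of each gene list's tested members, miR-150 minus control, with 95% intervals over the 8 arrays; the number tested is in parentheses and lists past an adjusted p of 0.05 by camera at the preset correlation are red. Cholesterol synthesis lay lowest at -1.16 and involution and acute phase genes highest at 1.09.

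In total 14 of 29 lists passed camera at the preset correlation, 9 down and 5 up, 0 passed with an estimated correlation, and 17 passed fry, 13 of the 14 among them. By the exact permutation test of list means, which does not compare a list with other genes, 19 lists reached the smallest p of 0.029 (adjusted p = 0.044), all 14 among them. The others were lactose synthesis, prolactin and STAT5 signalling, glycolysis and hypoxia, reported miR-150 targets and neutrophils. Splits of the arrays that mixed the genotypes gave up to 19 lists by camera at the preset correlation, or up to 13 where each side held 2 arrays of each genotype, and 0 genes.

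Several of the largest differences lay outside these lists. Slc5a8, a sodium-coupled monocarboxylate transporter, rose 11.2-fold (7.21 to 17.5, adjusted p = 0.000248), the chloride channel accessory genes Clca3a2 and Clca3a1 9.79-fold (4.96 to 19.3) and 8.14-fold (4.66 to 14.2), the acute phase gene Orm2 7.69-fold (5.05 to 11.7) and the aminopeptidase gene Anpep 7.34-fold (4.68 to 11.5). Angptl4, an inhibitor of lipoprotein lipase, rose 7.15-fold (4.71 to 10.9) and Pdk4, a kinase that inhibits pyruvate dehydrogenase, 6.53-fold (4.79 to 8.90). Rnase1, C4b and Muc4 rose 5.58-, 5.57- and 4.80-fold. Falling most were Adamts5, a secreted protease, by 10.1-fold (6.07 to 16.8), Plpp4 by 8.21-fold (4.86 to 13.9), Ddah1 by 7.35-fold (3.60 to 15), Gsdmc by 6.22-fold (3.52 to 11), Drd4 by 4.80-fold (3.26 to 7.06), the transferrin receptor Tfrc by 4.64-fold (3.73 to 5.78) and the sodium-proton exchanger Slc9a4 by 4.56-fold (2.47 to 8.40). Slc9a4 did not pass with the description number as a covariate (-1.88).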

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

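The values of chromosome 14 with arrays left out were computed only after the result was seen; the other tests of explanations below were fixed after the strongest genes had been seen but before their own results.

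For genes, only the genotype split among the 35 splits of the 8 arrays into 4 and 4 gave as many as its 4244 clusters. The highest other gave 0. Each other split mixed the genotypes, so their difference widened the spread within its sides and held its count down. The top rank among 35 is the most this design can give, so the count cannot exclude a chance division. For lists by camera at the preset correlation, the count does not argue against a chance division. Of the 35 splits, 5 gave as many as the real 14, and the highest other gave 19. The other 4 of these kept 3 arrays of a genotype together and so part of the genotype difference, and splits with 2 arrays of each genotype on each side gave at most 13. The split of the 4 youngest from the 4 oldest mice gave 13 lists and 0 genes.

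Fatty acid and cholesterol synthesis genes, 41 in all, were lower in miR-150 mice by a mean of -1.13 (-1.31 to -0.94). The shift was -1.25 (-1.49 to -1.001) with mouse age as a covariate and -1.11 (-1.41 to -0.82) with the description number. These values argue against a linear effect of either as the whole cause. Within genotypes the age slope leans most on miR-150 replicate 4, aged 80 days against 65 to 67 for the other miR-150 mice. Age largely went with genotype, so a part played by age cannot be told apart. The description numbers were 6, 5, 18 and 4 in controls and 22, 21, 10 and 23 in miR-150 mice. They largely went with genotype too, so a part played by what they record cannot be told apart either. A loss of adipocytes is argued against by 7 bright adipocyte markers without Lpl and Cd36, with a shift of 0.035 (-0.20 to 0.27). They were Fabp4, Car3, Pparg, Lipe, Pnpla2, Slc2a4 and Aqp7, and their mean averages a rise of Lipe (0.59) and a fall of Pparg (-0.48). A lower share of luminal cells as a whole is argued against by a luminal shift of 0.57 (0.34 to 0.80). The bound set for both was -0.56, so these explanations needed a lower value. Luminal markers moved unevenly, Kit by 2.60 and Elf5 by -0.20, which did not pass. A change among kinds of luminal cells was not tested. The fatty acid and cholesterol lists shifted by -1.12 and -1.20 after quantile normalization and by -1.08 and -1.15 after median centring. Camera at the preset correlation called both lists in both settings. At an estimated correlation neither list passed (camera adjusted p = 0.218 and 0.185 with the values as deposited). The deposited columns already had nearly equal quantiles, so these settings could change little. They argue only against a scaling difference left in the deposited values. The authors' background correction, normalization and summarisation were not tested, and an effect of the genotype stays a hypothesis.

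Involution and acute phase genes were higher by 1.09 (0.74 to 1.43). With age as a covariate the shift was 1.24 (0.72 to 1.77) and with the description number 1.14 (0.59 to 1.69). These values argue against a linear effect of either as the whole cause. A part played by age, or by what the description numbers record, cannot be told apart here either. Neutrophils or macrophages in the preparation cannot be told apart from a change in the epithelium: the macrophage shift was 0.35 with an upper bound of 0.63, above the limit of 0.54 set for exclusion, while neutrophil markers without Ltf shifted by 0.16 (0.05 to 0.27), with S100a8 at 1.56 and the other 8 at -0.10 to 0.13. The control median intensity of the macrophage markers was 87.6 and of the neutrophil markers 46.9, near the dim end of the scale, which keeps this open. With age as a covariate the macrophage shift was 0.20.

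A run of 38 neighbouring genes on chromosome 14, 37 of them predicted genes with Gm names, held 27 lower and 2 higher calls, a median log2 difference of -1.09 and a mean of -1.04 (-1.81 to -0.26). It was found by counting calls in windows of 15 genes, where 11 lower calls exceeded the highest of 1000 shuffled gene orders, 10. Members deviated together within genotypes, with a median correlation of 0.961 against 0.045 for as many random genes. Near-identical copies read by many clusters would give such a value, so the calls may count a few transcripts many times. The deviation of control 4 alone could give a high value as well. The correlation was not computed without control 4, so it does not settle the cause. Control 4 stood apart at 0.94 above the control mean, with the other controls at -0.26 to -0.41 and miR-150 arrays at -0.98 to -1.09; without control 4 the shift was -0.72 (-0.85 to -0.59), with 31 lower and 3 higher, while without miR-150 3 only 10 were lower. Age cannot be told apart, with -1.04 (-2.33 to 0.25) as a covariate, and a strain difference on the mixed background was not tested.

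Of 328 groups of 4 arrays, 18 held an array whose gap to the nearest other was a larger part of the group's range than the 95% critical value of Dixon's test, where chance gives about 1 in 20. Among lists, these were luminal epithelium on control 4 (0.830, low) and miR-150 4 (0.865, high), macrophages on control 4 (0.908, low) and miR-150 4 (0.910, low), and myoepithelium on control 1 (0.935, high). Single genes on miR-150 4 were Slc5a8 (0.913, high), Kit (0.838, high) and Slc9a4 (0.859, low). On miR-150 1 they were Cyc1 (0.870), Zfp36 (0.930) and Slc25a1 (0.905), all high. Control 4 was low for Orm2 (0.955) and Krt18 (0.834), and control 1 high for Cldn4 (0.900) and Zbp1 (0.830) and low for Csn2 (0.844). Pax5 was high on miR-150 2 (0.900) and Ddah1 low on miR-150 3 (0.836).

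Among 13619 clusters with several or no listed gene symbols, which the comparisons left out, 621 passed the threshold, 357 higher and 264 lower in miR-150 mice. Of 1272 with several symbols 138 passed, 63 higher and 75 lower.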

How the results depend on the processing

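The exact permutation test of list means was the only alternative here chosen after the data were seen. The count of genes kept within 1.5 times of 4244 in every alternative but 2: with the description number as a covariate 2070 passed (1056 higher, 1014 lower), and with a 2-fold minimum 379 (173 higher, 206 lower), which adds a criterion. The cause of the former was not tested. Leaving out each array gave 3137 to 4318, and age as a covariate 3556. Mir150 passed throughout, at 1.14 to 1.49. Of 106 named genes that passed, 77 kept their call in every alternative and 94 with any array left out; 24 lost it with the description number and 14 with age, and 0 changed sign. Of 14 lists, 0 kept their call with an estimated correlation, 10 kept it in every other alternative fixed in advance, and 11 with any array left out; the exact test called 19. The first principal component held 52.6% over all clusters.

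List shifts that changed sign passed neither with all arrays and no covariate nor in the setting named, and the cause was not tested: T and NK cells with quantile normalization (0.002) and median centring (0.003), skeletal muscle with median centring (0.004) and the 75th percentile filter (0.029), and, with age, the unfolded protein response (-0.22), myoepithelium (0.11) and ribosomal proteins (-0.047). With each array left out, shifts ranged from -0.032 to 0.001 for T and NK cells, -0.037 to 0.228 for the unfolded protein response, -0.091 to 0.014 for immediate early genes, -0.264 to 0.015 for myoepithelium and -0.035 to 0.003 for skeletal muscle. The unfolded protein response, myoepithelium, ribosomal proteins (0.12) and glycolysis (-0.14) passed without miR-150 replicate 4, and the first pair also with the description number (0.31 and -0.42).

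The seed site test and its alternatives were not run. Signal over background was not measured in the values used, so how far dim genes limit the folds is not known.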

Other observations

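All tests in this part were chosen only after some result was seen: the gene list after 6 of its genes, and the neighbour windows after the calls.

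Some genes of fatty acid oxidation rose in miR-150 mice, where the synthesis genes fell. A list of 44 genes of fatty acid oxidation and targets of the PPAR receptors was written after Pdk4, Angptl4, Acadl, Acot1, Acot2 and Plin2 had been seen among the rises, and those 6 were left out of its test. Of the 29 others tested, 12 rose, Ppara fell (-0.22 ± 0.05) and the rest did not pass. Cpt1a, the carnitine acyltransferase that admits long-chain fatty acids to mitochondria, rose 2.9-fold (adjusted p = 0.000662). The carnitine carrier Slc25a20 rose 2.11-fold, and Hadhb and Hadha, the subunits of the trifunctional protein, 1.79- and 1.75-fold. Markers of luminal epithelium shifted by 0.57 (0.34 to 0.80) and those of macrophages and dendritic cells by 0.35 (0.08 to 0.63) on the same arrays. The oxidation list's mean shift was 0.33 (0.15 to 0.51), with a camera p of 0.000183 and p = 0.148 with an estimated correlation. A list-wide rise is consistent with the former p and was not shown with the latter, and it remains a hypothesis.

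On chromosome 13, windows of 15 neighbouring genes held 9 and 8 lower calls. Neither exceeded the highest of 1000 shuffled gene orders, 10, and their 95th percentile was 8. Histone genes were among these calls, but histones were not tested as a list. Named after their values were seen, H2ac14 fell by 1.62 ± 0.19 and H2ac10 by 1.62 ± 0.20 on the log2 scale, from intensities of 4710 and 3273. On chromosome 12 a window with 11 higher calls in 15 equalled the highest shuffled order, 11, where the 95th percentile was 9.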
